A study of Mus musculus with 63 samples.

How the data were processed

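The series holds single immune cells from mouse brain, profiled by MARS-seq on 63 plates of 384 wells. The deposited tables of each plate hold counts, as whole numbers per gene and well, with no normalization by the authors, and a deposited table per well gives the number of sorted cells, the total counts and the number of genes. That number of genes equalled the genes above 0 in the count table for all 24192 wells. The read processing used bcl2fastq 2.15.0.4 and genome mm10 per the submitters' processing notes, and the aligner and the annotation are not given in the sources used here. The tables held 52634 names, of which 92 were ERCC spike-ins. The count tables are read as UMI counts, as MARS-seq makes them. Gene positions came from GENCODE vM21, on GRCm38, the same assembly as mm10. Annotations of cells by the authors are not used here.

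A well was kept as a cell when it had received 1 cell, held at least 300 UMIs and had at most 20% mitochondrial counts. This removed 3854 wells for low counts and 1478 for mitochondrial content and left 18608 cells, between 104 and 371 per plate, with a median of 415 to 1381.5 UMIs per cell and plate. The mitochondrial limit removed 0 to 24 wells per plate of TREM2-/- mice and 23 to 73 per plate of TREM2+/+ mice in the TREM2 experiment. On the plate of GFP+ mouse 230 it removed 162 of 380 wells. No alternative changed the mitochondrial limit, so the genotypes are compared on cells filtered to different extents. In the TREM2 experiment the limit of 300 UMIs removed 15 to 276 wells per plate of TREM2-/- mice. Per plate of TREM2+/+ mice it removed 18 to 57. None of the 252 empty wells reached 300 UMIs, and their median per plate ranged from 1 to 86 UMIs. Plates received 1 cell per well by sorting, so no tool for doublets was run. A count of 0 for a gene in a cell was common at this depth, so genes were compared in sums over the cells of a mouse and class, not cell by cell.

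Cells were scaled to 1000 UMIs and log-transformed, 1500 variable genes and 30 principal components were taken, and Leiden clusters were made from 15 nearest neighbours at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). Clusters were named from 12 marker lists and joined into the microglia, macrophage, lymphocyte and neutrophil classes. The marker lists, the gene lists, the comparisons, the tests, the rule for named genes and most alternatives were chosen before the data were examined. The clustering settings were chosen after looking at clusters, and a finer clustering at resolution 2 was used as an alternative. The microglia class joins resting and activated clusters, and their sizes are not tested between genotypes, since the genotype changes the genes that define them.

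Samples were grouped by the labels of experiment, genotype, antibody and sort. The replicate was the mouse, and plates of 1 mouse were summed. The 6 mice of each antibody in the CD45+ experiment fell into the plate series AB6 and AB7, with 3 mice per antibody in each, and the series entered that fit as a covariate. In the TREM2 experiment the AB10 series held all 12 mice and the AB9 series 10. Each anti-PD-L1 mouse there had 3 plates, with a further AB10 plate that no IgG2b mouse had, and each IgG2b mouse 1 or 2. Antibody effects are therefore not separated from these further plates, and AB10 plates alone keep them. The labels of 2 chimera plates, plate 1 of mouse 267 and plate 1 of mouse 295, disagreed about the sort, and these plates with their 415 cells entered no comparison. Ages of 7 months for mice 507 and 508 and 8.5 months for the other mice of the TREM2 experiment were left uncorrected and tried as an alternative.

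UMI counts were summed per mouse and class where at least 20 cells were present. Microglia libraries held 139227 to 1166066 UMIs of tested genes and macrophage libraries 18274 to 121467. Genes were filtered with filterByExpr, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05. The genotype fits had the antibody as a covariate, and the antibody effects and their difference came from 1 fit with a mean per group. Errors of log2 fold changes are standard errors from the test statistic. CPM values are counts per 1e6 counts of the tested genes after TMM scaling, with library sizes recomputed after the filter. The 19 gene lists and the marker lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1), and adjusted over the lists of a comparison. The difference of the genotype effect between classes was tested with limma on the log2 CPM in macrophages minus that in microglia of the same mouse. Shares were compared with exact permutation tests of the mean difference, two-sided, with labels permuted within antibody, genotype or plate series. Shares of single mice carry exact (Clopper-Pearson) 95% intervals, and a share of 0 an upper limit of 3 counts over all cells.

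Named genes were, for each comparison, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 50 CPM, genes without a described name, ribosomal and mitochondrial genes being counted but not named. Members of the fixed lists past the threshold were added, at most 4 per list. Where fewer than 10 genes passed, all of them and the 4 smallest p-values on each side were named. Trem2, Cd274, Apoe, Clec7a, Cst7, Msr1 and Ccr2 were given in each comparison where they were tested.

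The fits were tested on simulated data, drawn from the means, dispersions and library sizes of each fit with 200 genes changed. At a change of 2-fold the genotype fit recovered 80.6% of the changed genes in microglia and 98.1% in macrophages, the antibody fits 50.0% and 44.6% in microglia of TREM2+/+ and TREM2-/- mice and 45.2% and 73.3% in macrophages, and the tests of the difference 17.5% and 37.1%. The CD45+ fit recovered 68.3% and the sort comparison 9.09%. At 1.5-fold the recovery was 27.3% for genotype in microglia and 24.6% for the CD45+ fit. The changed genes lay among 7249 tested genes in the microglia genotype fit but among 476 in the macrophage one. The simulated macrophage fit called 139 genes and the real one 1. A larger changed part eases the adjusted threshold, so recovery in macrophages does not give the power of a fit with few calls. Camera called 0 of 20 unchanged lists of 15 genes, and fry called 1 of 20 in the genotype fit of macrophages. The simulated data held no correlation between the genes of a list, so they do not test camera where such genes vary together.

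Alternatives were library size alone, DESeq2 1.42.0, no filter beyond a count of 1, at least 500 UMIs per cell, all cells of the sort summed, finer clusters, sex as a covariate, female mice only, AB10 plates only, single plate series or no plate series term in the CD45+ experiment, leaving out each mouse, and for the chimeras the CD45+ plate of the WT mouse added and myeloid cells only. Chosen after seeing the data were AB9 plates only, AB10 plates only for the shares, and leaving out the 2 mice of 1 plate, the 2 mice aged 7 months, the border macrophage cluster, 1 plate of mouse 997, and the mitochondrial genes with the 2 most abundant genes. Library size alone moved the median change of all genes to -0.14 for genotype and to 0.38 for the antibody in TREM2-/- mice, both in macrophages, and to 0.17 for the antibody in TREM2+/+ macrophages. Among the gene fits, sex as a covariate and female mice only were tried for the genotype effect alone. The macrophage class of the CD45+ experiment was not fitted, since no mouse had 20 such cells. Figures were drawn with matplotlib 3.10.9.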

Results

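Single cells sorted from the brains of mice, of the 5xFAD model of amyloid disease apart from an untreated WT chimera, were profiled by MARS-seq, a plate-based method that counts unique molecular identifiers (UMIs) of 3' transcript tags in each well. The 63 plates held 24192 wells, of which 23940 received 1 cell and 252 were left empty. After filtering, 18608 cells remained, 18193 of them on plates whose labels gave a group. The TREM2 experiment held 12 mice on 28 plates, sorted as CD45+CD11b+Tmem119neg-mid cells, with 3 mice in each combination of TREM2 genotype (-/- or +/+) and antibody (anti-PD-L1 or the control IgG2b). Its 8160 cells had a median of 1017 UMIs, and its mice contributed 211801 to 1300715 UMIs each. The CD45+ experiment held 6 mice given anti-PD-L1 and 6 given control IgG, all TREM2+/+, with 7237 cells, a median of 894 UMIs per cell and 220465 to 1019048 UMIs per mouse. The chimera experiment held 6 mice whose blood-borne cells carried GFP, sorted as CD45+GFP+ or as CD45+ cells, with 2796 cells, a median of 972.5 UMIs per cell and 170614 to 874511 UMIs per sort and mouse. Clusters of all cells were named from marker genes as microglia, macrophages (monocytes, monocyte-derived and border macrophages together), lymphocytes or neutrophils. Anti-PD-L1 blocks an immune checkpoint ligand, and the series asked which brain immune cells change under it and whether TREM2, a receptor of microglia and macrophages, is needed.

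Trem2 RNA in the microglia class averaged 98.3 ± 15.9 CPM (counts per 1e6 counts of tested genes; SD, n = 6) in TREM2-/- mice, between 75.8 and 115 in each mouse, against 3545 ± 376 CPM (n = 6) in TREM2+/+ mice, between 2943 and 3948 in each. The fall of -5.18 ± 0.12 (log2, SE) had an adjusted p of 1.7e-28. Trem2 lies on chromosome 17 from 48346401 to 48354147 (mm10). The labels do not state which part of the gene was removed, and 3' tags outside a removed part would still be counted, so the remaining counts do not test the knockout.

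The microglia class of TREM2-/- mice, summed over its clusters, held far less RNA of the genes that mark disease-associated microglia (DAM). Spp1, which encodes the matrix protein osteopontin, had 45.1 ± 28.8 CPM in TREM2-/- mice against 584 ± 149 CPM in TREM2+/+ mice (SD, n = 6 each), a change of -3.49 ± 0.21. Gpnmb, a lysosome-associated glycoprotein of lipid-laden phagocytes, changed by -3.49 ± 0.35, and Itgax, which encodes CD11c, by -2.74 ± 0.15. Cst7, an inhibitor of lysosomal cathepsins on chromosome 2 (150570415 to 150578944), had 576 ± 115 CPM against 2952 ± 644 CPM (n = 6 each), a change of -2.34 ± 0.12. Cells of the clusters in the class were counted over the mice of a group and not tested, because genes that fell also lead these clusters. The groups held 1020 and 2595 cells of TREM2-/- mice under IgG2b and anti-PD-L1, and 1841 and 2704 of TREM2+/+ mice. The cluster led by Spp1, Gpnmb and Cst7 held 2 cells of TREM2-/- mice under IgG2b and 3 under anti-PD-L1, against 164 and 257 of TREM2+/+ mice, and the cluster led by Cst7, Ctsd and Ank 147 and 447 against 1028 and 1232, so the changes of the class do not separate a shift between clusters from a change within cells. Tmem119, a marker of resting microglia that the sorting gate also used, was higher in TREM2-/- mice, at 978 ± 118 against 510.4 ± 188 CPM (n = 6 each). Between the genotypes, 785 of 7520 tested genes passed an adjusted p of 0.05 (edgeR, two-sided), with 306 higher and 479 lower in TREM2-/- mice.

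The further largest falls among genes of at least 50 CPM were those of Mamdc2 (-3.11), Fabp5 (-2.61), a carrier of fatty acids, Cd74 (-2.42), H2-Aa (-2.29) and Il4i1 (-1.92). The largest rises were those of Stab1 (1.72 ± 0.16, with 119 ± 16.6 against 35.5 ± 13.7 CPM, n = 6 each), Slc40a1 (1.54), the iron exporter, Ecscr (1.39), Crybb1 (1.30), AC149090.1 (1.27), Malat1 (1.05), Lyl1 (1.02), Maf (1.00), Fam105a (0.99) and Tmem119 (0.95). AC149090.1 is an exception, named here although its name describes no gene. A further 89 genes that passed carried names without a described gene, or were ribosomal or mitochondrial, and are counted but not named. Sex was not balanced, since all TREM2-/- mice and 2 of the TREM2+/+ mice were female. With female mice only, 772 genes passed, and the rises were 2.28 for Ecscr, 2.02 for Crybb1, 3.00 for Mrc1 and 1.52 for Tmem119. Within the plate series named AB10, 554 genes passed, and within the series named AB9, which held 10 of the mice, 159 passed. On the AB9 plates Ecscr (adjusted p = 0.14), Gpr34 (0.059), Apoe (0.059), Oasl2 (0.18), Ifi27l2a (0.38), Ndufa1 (0.46), Cox8a (0.32), Jun (0.21), Junb (0.30) and Pdcd1 (0.15) were no longer past the threshold.

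In lists of genes fixed before the data were examined, the late DAM list, the stage that depends on TREM2 in mouse models, had 26 of 27 genes tested, of which 0 rose, 25 fell and 1 was not past, or 26 fell adjusted over the list alone (camera adjusted p = 1.8e-50, and adjusted p = 0.02 with an estimated correlation). Of 11 early DAM genes, the stage reached without TREM2 in those models, 0 rose, 10 fell and 1 was not past, or 11 fell adjusted over the list alone (adjusted p = 7.9e-19, and adjusted p = 0.027 with an estimated correlation). Early DAM genes included Tyrobp (-0.82), the signalling partner of TREM2, Apoe (-0.76, 10328.6 ± 869 against 17529.8 ± 4289.5 CPM, n = 6 each), a lipid carrier and risk gene, and B2m (-0.71). Of 7 tested genes of MHC class II, which presents antigen to T cells, 6 fell and 1 was not past, among them H2-Ab1 (-1.61) and H2-Eb1 (-1.44), with the same counts adjusted over the list alone (adjusted p = 5.8e-13, and adjusted p = 0.02 with an estimated correlation). With all cells of the sort summed instead of the microglia class, which adds the macrophages, Cd74 (0.72), H2-Aa (0.98), H2-Ab1 (1.03) and H2-Eb1 (1.32) were higher in TREM2-/- mice.

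Of 23 homeostatic microglia genes, 14 rose, 0 fell and 9 were not past, or 16 rose adjusted over the list alone, including Tmem119, Txnip (0.87) and Gpr34 (0.51); the list had an adjusted p = 1.1e-11 and an adjusted p = 0.076 with an estimated correlation. Of 26 lysosome and cathepsin genes, 1 rose, 15 fell and 10 were not past, or 1 rose and 19 fell adjusted over the list alone, including Gusb (-0.79) and Npc2 (-0.67), with an adjusted p = 0.076 with an estimated correlation. Of 17 tested lipid and cholesterol genes, 2 rose, 8 fell and 7 were not past, with the same counts adjusted over the list alone, including Lpl (-1.90), a lipase of microglia near plaques, and Srebf2 (-1.70), with an adjusted p = 0.079 with an estimated correlation. Of 12 glycolysis and hypoxia genes, 1 rose and 7 fell, or 1 and 8 adjusted over the list alone, including Hif1a (-0.71) and Pkm (-0.69), with an adjusted p = 0.076 with an estimated correlation. Of 21 nuclear genes of oxidative phosphorylation, 0 rose and 7 fell, or 10 fell adjusted over the list alone, including Ndufa1 (-0.84) and Cox8a (-0.66), with an adjusted p = 0.095 with an estimated correlation. Of 26 tested interferon response genes, 0 rose and 6 fell, or 9 fell adjusted over the list alone, including Oasl2 (-1.14) and Ifi27l2a (-0.68), with an adjusted p = 0.37 with an estimated correlation. Of 13 tested MHC class I genes, 0 rose and 6 fell, or 7 fell adjusted over the list alone, including H2-D1 (-0.65), with an adjusted p = 0.079 with an estimated correlation. Oasl2, Ifi27l2a and Gpr34 were not past the threshold with all cells of the sort summed.

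Smaller or mixed lists followed. Of 21 tested scavenger and phagocytic receptor genes, 4 rose and 7 fell, or 5 and 8 adjusted over the list alone, with Mrc1 higher (2.00 ± 0.36) and Axl (-1.72) and Clec7a (-1.01 ± 0.11) lower. Of 3 tested genes of the border macrophage list, 2 rose (camera adjusted p = 0.00062, and adjusted p = 0.027 with an estimated correlation). Stab1 and Mrc1 are markers of macrophages at the borders of the brain, and Mrc1 averaged 23.4 ± 8.84 against 5.44 ± 3.82 CPM (SD, n = 6 each). The finer cluster led by Mrc1, Pf4 and Stab1 had 3173 CPM of Mrc1 and 1876 CPM of Stab1. It held 5.79% of the sorted cells in TREM2-/- mice against 1.70% in TREM2+/+ mice. For Stab1 and Mrc1, a change within microglia is therefore not told apart from counts of border macrophages in the microglia class. Of 11 tested inflammatory cytokine genes, 0 rose and 3 fell, with the same counts adjusted over the list alone, including Cxcl16 (-0.65). Of 17 tested immediate early and dissociation stress genes, 3 rose and 0 fell, or 4 and 1 adjusted over the list alone, including Jun (0.89) and Junb (0.73). Of 9 tested immune checkpoint genes, 0 rose and 3 fell, or 2 and 4 adjusted over the list alone, including Pdcd1 (-1.13), which encodes PD-1. Cd274, which encodes PD-L1, fell by 0.57 with an adjusted p of 0.048. That call was lost under DESeq2 (0.13), under library size alone (0.091) and without mouse 487 (0.079), 507 (0.056), 489 (0.14), 490 (0.069), 508 (0.073), 492 (0.067), 495 (0.066), 493 (0.17) or 498 (0.076) in turn. The 8 tested cell cycle genes had 0 past the threshold in edgeR, and among the 8 tested monocyte-derived macrophage genes 1 rose and 2 fell. Msr1 and Ccr2 had too few counts to be tested in microglia.

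In the macrophage class, Trem2 was the 1 gene of 570 past an adjusted p of 0.05 (edgeR), with 43.4 ± 46.6 CPM in TREM2-/- mice, between 0 and 134 in each, against 679 ± 91.03 CPM in TREM2+/+ mice, between 560.02 and 838 (SD, n = 6 each), a change of -4.07 ± 0.33. Apoe changed by 0.32 ± 0.15 (adjusted p = 0.46), Clec7a by -0.38 ± 0.31 (0.78) and Ccr2, the receptor that draws monocytes from blood, by 0.15 ± 0.25 (0.89). The smallest p-values after Trem2 were those of Mir6236 (1.29, adjusted p = 0.060), Id2 (-1.02, 0.22), Lsp1 (-0.72, 0.22), Srgn (-0.70, 0.22), Gm26917 (0.61, 0.22), C1qc (0.41, 0.31) and Mgl2 (0.88, 0.40). Cd274, Cst7 and Msr1 had too few counts to be tested. Over the counts of all genes, Cst7 had 10.8 to 62.8 CPM in TREM2-/- mice. It had 24.6 CPM in TREM2+/+ mouse 492 and 145 to 335 CPM in the other TREM2+/+ mice. These values rest on 1 to 14 UMIs per mouse, so a fall of Cst7 in macrophages was neither tested nor excluded. An unadjusted p under 0.05 was reached by 52 genes, and DESeq2 called 2 genes. Without mouse 488 or 498, 2 genes passed, and without mouse 487, 490, 508, 492, 493, 494 or 495, 3 genes passed. Each gene list had an adjusted p of at least 0.51 with an estimated correlation.

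The genotype effect was then compared between the classes by a test of the difference, chosen after seeing the data. Of 549 genes tested in both classes, 46 had an effect that differed at an adjusted p under 0.05 (limma). Among these, 36 had been called in microglia and the other 10 in neither class. Cd74, the invariant chain of MHC class II, changed by -2.42 in microglia and by 0.21 in macrophages, a difference of 2.45 ± 0.25. H2-Aa differed by 2.34 ± 0.32 and Axl, a receptor for dying cells, by 1.91 ± 0.26.

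**Figure D1:**
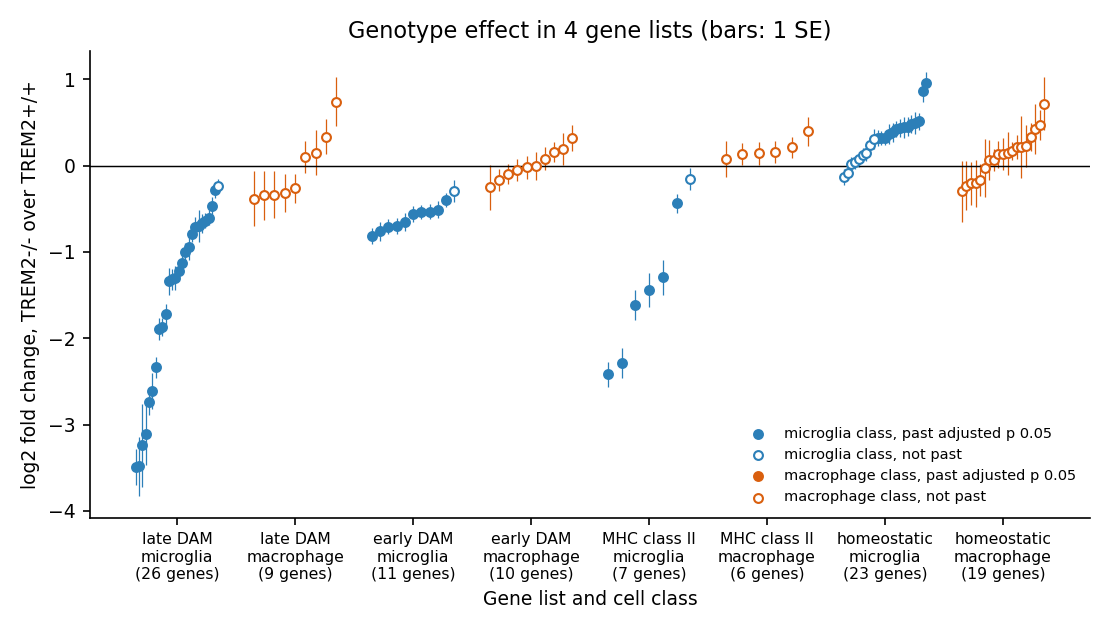
Log2 fold change of TREM2-/- over TREM2+/+ mice (vertical axis) for each tested gene of 4 gene lists in the microglia and the macrophage class (horizontal axis); points are genes, filled where past an adjusted p of 0.05, and bars are 1 SE. In microglia 25 of 26 late DAM genes are filled, and in macrophages 0 points are filled.

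Macrophages took a larger share of the CD45+CD11b+Tmem119neg-mid cells in TREM2-/- mice. They made up 18.5 ± 5.29% of the cells of TREM2-/- mice (SD, n = 6, from 11.1 to 26.9%) and 6.21 ± 2.80% of those of TREM2+/+ mice (n = 6, from 4.16 to 11.8%), a difference of 12.3 percentage points (exact permutation p = 0.005, two-sided, the smallest the test can give; 0.01 adjusted over 4 classes). The microglia share was 77.2 ± 5.21% against 90.4 ± 4.32% (n = 6 each, exact permutation p = 0.005, the smallest possible). Within the AB9 plates the macrophage difference was 14.4 percentage points and within the AB10 plates 11.5. Among female mice it was 13.3, with an exact p of 0.0625, the smallest that subset can give. The highest share, 26.9%, was that of TREM2-/- mouse 507, and the other TREM2-/- mice had 11.1 to 20.4%. The only plate of mouse 507 kept 145 of 380 wells, with 233 removed for low counts. Its median was 65 UMIs in wells with a cell and 63 in empty wells. Plate 3 of TREM2-/- mouse 508 kept 104 wells, with 276 removed for low counts. Finer clusters were compared as well. The cluster led by H2-Eb1, H2-Aa and Cd74 held 9.20% against 2.38% of the cells (exact permutation p = 0.005), the cluster led by the border macrophage genes Mrc1, Pf4 and Stab1 5.79% against 1.70% (0.005) and the monocyte-like cluster led by Plac8 and Ear2 2.06% against 1.13% (0.025). The Cd209a cluster held 1.44% against 1.00% (0.21). The cluster led by H2-Eb1 also had Ccr2, Mrc1 and Ms4a7 among its leading genes. Its mean log2 fold over the other clusters was 1.09 for the border macrophage markers and 0.372 for the monocyte markers. The border macrophage cluster had 3.77 for the border macrophage markers. Leaving out the border macrophage cluster thus may not remove all border macrophages. Lymphocyte shares differed by 0.0943 percentage points (exact permutation p = 0.87) and neutrophil shares by 0.852 (0.23).

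**Figure D2:**
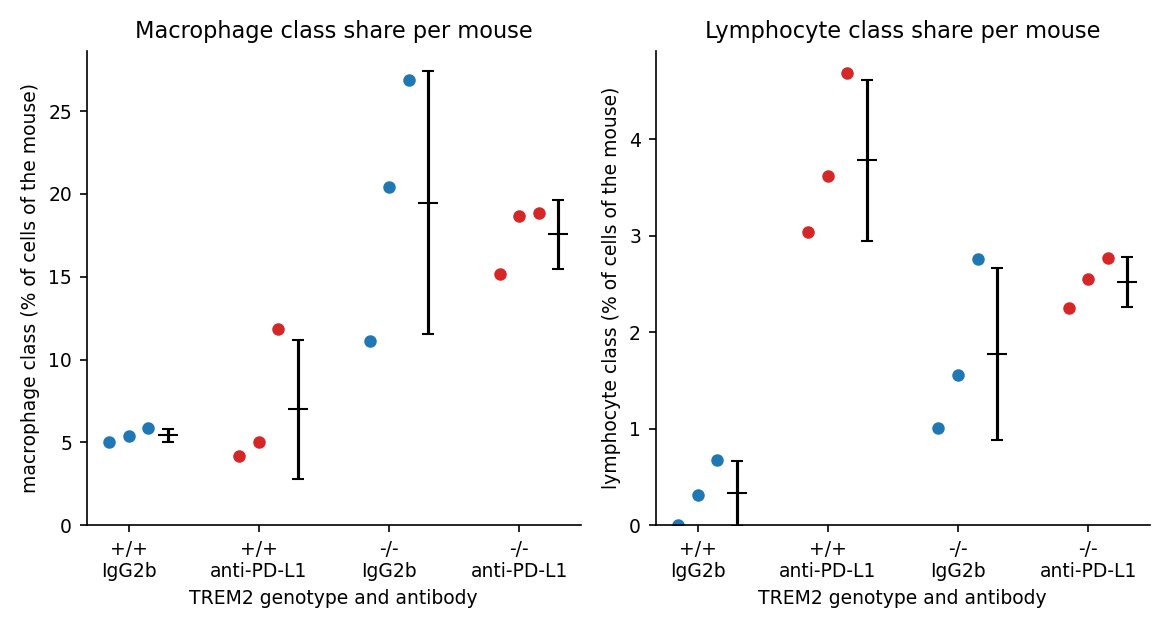
Share of the cells of each mouse in the macrophage class (left) and in the lymphocyte class (right), in percent on the vertical axes, by TREM2 genotype and antibody on the horizontal axes; points are mice (3 per group) and the bar beside them is the mean with 1 SD. The TREM2-/- mice lie from 11.1 to 26.9% macrophages and the TREM2+/+ mice from 4.16 to 11.8%.

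Under anti-PD-L1, Fos and Ptgds rose in the microglia of TREM2+/+ mice. Fos, an immediate early gene that answers stimulation and also tissue dissociation, had 26.9 ± 20.4 CPM under anti-PD-L1 and 0.452 ± 0.783 CPM under IgG2b (SD, n = 3 each), from 89 UMIs against 1 UMI (adjusted p = 0.0082). Ptgds, a prostaglandin synthase abundant in the meninges, had 28.6 ± 19.2 against 1.40 ± 0.0525 CPM (n = 3 each), from 98 UMIs against 3 (adjusted p = 0.040). These 2 genes were the only ones of 7872 past the threshold in edgeR, 323 had an unadjusted p under 0.05, and DESeq2 called 0. Fos was lost without mouse 492 (adjusted p = 0.088) or 494 (0.099), and Ptgds without mouse 492 (0.21), 494 (0.24), 495 (0.18), 493 (0.073) or 489 (0.071) and with at least 500 UMIs per cell (0.097). Without mouse 495, which held the 1 UMI of the control group, the fitted change of Fos was 7.32, which is no bound. The count of genes was 0 without mouse 492 or 494, 1 without 489, 4 without 487 or 496, 6 without 490 or 507, 7 without 508 and 11 without 493. Of 18 tested immediate early genes 1 rose, or 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.63 with an estimated correlation). Trem2 (-0.11 ± 0.13), Apoe (-0.17 ± 0.15), Clec7a (-0.26 ± 0.14), Cst7 (-0.14 ± 0.15) and Cd274 (0.22 ± 0.23) each had an adjusted p near 1.

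Values nearest to the threshold in these microglia were those of Dct (2.57, adjusted p = 0.070) and Rnu11 (2.24, 0.073) on the higher side. On the lower side they were Zfyve26 (-1.31, 0.15), Zfp113 (-1.68, 0.27), Gm42418 (-0.59, 0.38) and Srrm2 (-0.53, 0.40). AB10 plates alone gave 32 genes and AB9 plates alone 15.

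In the microglia of TREM2-/- mice, Jun, the partner of Fos in the AP-1 transcription factor, rose by 1.57 ± 0.24 under anti-PD-L1 (adjusted p = 0.0016), from 73.8 ± 20.5 to 237 ± 35.6 CPM (SD, n = 3 each). Fos changed by 4.34 ± 0.86 (adjusted p = 0.056), Rnu3b1 by 6.50 (0.14, with 0 UMIs under IgG2b, so that the fitted value is no bound) and Cox6a2 by 1.14 ± 0.26 (0.14), while Cst7 changed by 0.42 ± 0.17 (0.82). Jun was the 1 gene of 7872 past the threshold in edgeR and in DESeq2, and 451 had an unadjusted p under 0.05. Jun lost its call on the AB9 plates alone (1.37 ± 0.42, adjusted p = 0.52) and without the mice of 1 plate, 487 and 507 (1.44 ± 0.33, 0.78). Both alternatives leave mouse 488 alone in the TREM2-/- IgG2b group, and the size of the change stayed near that of all mice. The count of genes was 2 without mouse 487, 489 or 498, 3 without 488, 493 or 508, and 4 without 496. Of 18 tested immediate early genes 1 rose, or 5 rose adjusted over the list alone (adjusted p = 0.50 with an estimated correlation). The difference between the antibody effects of the genotypes passed for 0 of 7872 genes in edgeR and for 0 in DESeq2, with 353 at an unadjusted p under 0.05. Cox6a2 (1.20), Chid1 (2.99), H2-Ob (1.25) and Ms4a6b (-1.77) were among the smallest p-values of that test, and Fos and Jun were not.

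In the macrophage class of TREM2+/+ mice, Apoe fell by 0.98 ± 0.19 on the log2 scale under anti-PD-L1 (adjusted p = 0.014), from 32791.9 ± 8638 to 16641.4 ± 998 CPM (SD, n = 3 each). Tmem86a (-1.81), Mef2c (-1.60) and Aif1 (-1.31), a calcium-binding protein of macrophages and microglia, also fell, and Gm11478 (2.50) and Tmsb10 (1.93), an actin-binding peptide, rose, each with an adjusted p of 0.043. Those 6 were the genes past the threshold of 647 tested in edgeR, with 123 at an unadjusted p under 0.05. The count moved with each mouse left out. It was 0 without mouse 493, 494, 495, 496 or 498, 1 without 488, 489, 490, 507 or 508, 2 without 487 and 45 without 492. Mice 487, 488, 489, 490, 507 and 508 were TREM2-/- and are not part of this contrast. A lost call thus does not by itself show that a gene depended on a single mouse. Under library size alone 22 genes passed, 20 higher and 2 lower, and DESeq2 called 22, 13 higher and 9 lower. Of the 6 genes, library size alone kept 4, without Mef2c (adjusted p = 0.053) and Aif1 (0.076), and DESeq2 kept Apoe, the other 5 having been left out of its adjustment by its filter on low counts (unadjusted p from 0.00016 to 0.0051). Apoe was also not past the threshold without the border macrophage cluster (-0.92 ± 0.30, adjusted p = 0.28) or without a filter on genes (-0.47 ± 0.19, 0.94). On the AB10 plates alone it changed by -0.67 ± 0.27. Mice 492 and 494 had under 20 cells there, which left mouse 495 alone in the IgG2b group. With all cells of the sort summed, most of them microglia, Apoe changed by -0.25 ± 0.16 (adjusted p = 0.98), which is no value of macrophages alone. Taking out the border macrophage cluster also dropped mouse 495, which kept 18 cells, and without that mouse alone the change was -0.92 ± 0.21 (adjusted p = 0.11), so the lost call cannot be put down to the cluster. The make-up of the class differed between the groups. The border macrophage cluster held 21.9%, 22.6% and 51.4% of the class in IgG2b mice 492, 494 and 495 and 15.9%, 16.2% and 28.8% in anti-PD-L1 mice 493, 496 and 498, and the Cd209a cluster 25%, 3.23% and 0% against 27.3%, 21.6% and 18.9%. Crip1 (1.20, 0.066), Snord55 (0.88, 0.066) and Clec7a (-1.55, 0.066) were nearest to the threshold, and Trem2 (-0.32, 0.65), Cst7 (-0.85, 0.47) and Ccr2 (0.33, 0.69) were farther from it.

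In the macrophage class of TREM2-/- mice, 0 of 647 genes passed in edgeR, 55 had an unadjusted p under 0.05 and DESeq2 called 1. Without mouse 487, 1 gene passed, and without mouse 488, 5 passed. Abca9, a lipid transporter, had the smallest p among the described genes at -1.04 ± 0.25 (adjusted p = 0.14), and P2rx7 (-1.34, 0.34), Id2 (1.53, 0.34), Cd209a (1.23, 0.34) and Fos (1.37, 0.34) followed. Apoe changed by -0.17 ± 0.18 (0.80). Of 7 tested border macrophage markers, 0 rose and 0 fell over all genes, and 4 fell adjusted over the list alone (camera adjusted p = 7.2e-06, and adjusted p = 0.43 with an estimated correlation). The make-up of the class differed here too. The border macrophage cluster held 33.3%, 44.1% and 30.8% of it in IgG2b mice 487, 488 and 507 against 29.9%, 22.95% and 26.1% in anti-PD-L1 mice 489, 490 and 508, and the Cd209a cluster 3.03%, 5.08% and 5.13% against 10.9%, 13.7% and 8.96%, so the lower border markers and the higher Cd209a are not told apart from a shift between clusters. The test of the difference between genotypes passed for 0 of 647 genes in edgeR and for 0 in DESeq2, with 35 at an unadjusted p under 0.05, and 1 passed without mouse 488. Its values included Apoe (0.81, adjusted p = 0.59), Aif1 (1.43, 0.40) and Plac8 (2.72, 0.40).

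Macrophage shares of the gated sort with and without anti-PD-L1 differed by less than the spread between mice. They were 12.3 ± 6.50% under anti-PD-L1 and 12.5 ± 9.19% under IgG2b (SD, n = 6 each), a difference of -0.169 percentage points (exact permutation p = 0.965, two-sided). The sign turned without mouse 488 (0.0657), 489 (0.432), 493 (0.325), 496 (0.541) or 507 (1.69). Microglia differed by -1.51 percentage points (exact p = 0.605) and neutrophils by -0.418 (exact p = 0.57), and without mouse 487 by 0.329 and 0.0242. Lymphocytes, mostly of the T cell cluster, made up 3.15 ± 0.882% against 1.05 ± 0.996% (n = 6 each), a difference of 2.10 percentage points (exact permutation p = 0.015, and 0.06 adjusted over 4 classes). Within the AB9 plates, where mouse 488 was the 1 TREM2-/- mouse under IgG2b, this difference was 0.138 (exact p = 0.875) and within the AB10 plates 3.08 (exact p = 0.01). By genotype, in a comparison added after seeing the data, the lymphocyte share was 3.78 ± 0.833% against 0.330 ± 0.336% in TREM2+/+ mice and 2.52 ± 0.257% against 1.78 ± 0.894% in TREM2-/- mice (n = 3 each). The exact p was 0.1 in TREM2+/+ mice, the smallest that 3 against 3 mice allow, and 0.3 in TREM2-/- mice. Macrophages in TREM2+/+ mice changed by 1.57 percentage points (exact p = 1), and in TREM2-/- mice by -1.91 (exact p = 0.7).

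In the CD45+ experiment, which sorted all leukocytes without the Tmem119 gate, the microglia class held Trem2 at 2056 ± 254 CPM under anti-PD-L1 and 1933 ± 133 CPM under IgG (SD, n = 6 each), a change of 0.09 ± 0.10. Cst7 changed by 0.37 ± 0.12 (p = 0.0049 in edgeR, adjusted p near 1), Apoe by 0.22 ± 0.15, Clec7a by 0.21 ± 0.16 and Cd274 by 0.11 ± 0.43. Of 25 tested late DAM genes 22 had a positive change, with a median of 0.21, and 0 passed; camera gave an adjusted p = 1.5e-08, and an adjusted p = 0.10 with an estimated correlation. All 11 early DAM genes had a positive change with 0 past (adjusted p = 6.5e-08, and adjusted p = 0.13 with an estimated correlation). Of 8297 genes, 0 passed in edgeR and 0 in DESeq2, and 311 had an unadjusted p under 0.05 in edgeR, while 1 passed without IgG mouse 13. The smallest p-values of described genes were those of Il17ra (-0.68), Igkc (-2.76), an antibody light chain that microglia do not make, Mir705 (0.56), Lars2 (0.68) and Pear1 (1.45).

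Macrophages of the CD45+ experiment made up 0.877 ± 0.545% of cells under anti-PD-L1 and 1.54 ± 0.973% under IgG (SD, n = 6 each), a difference of -0.661 percentage points (exact permutation p = 0.09, two-sided, and 0.36 adjusted over 4 classes). Within the AB6 series the difference was -0.774 (exact p = 0.4) and within AB7 -0.547 (exact p = 0.1, the smallest possible, n = 3 each). Without IgG mouse 377 it was -0.987 (exact p = 0.005). Microglia made up 96.7 ± 0.867% against 94.4 ± 4.22% (exact p = 0.235), and lymphocytes 2.13 ± 0.603% against 3.85 ± 3.97% (exact p = 0.475). Without IgG mouse 997 the lymphocyte difference was 0.0313 percentage points instead of -1.72. With finer clusters the lymphocyte share under IgG was 2.149 ± 1.27%, and the difference -0.0218 (exact p = 0.935). The B cell cluster held 85 cells of the IgG mice, and the finer B cell cluster 10. A finer cluster left unnamed, led by Igkc and cell cycle genes and with 14 microglia markers detected, held 101 cells of the IgG mice.

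The GFP+ sorts of the chimeras, mixtures of lymphocytes, macrophages and neutrophils, held more RNA of monocyte genes and less of microglia genes than the CD45+ sorts. Ccr2, on chromosome 9 (124101950 to 124113557), had 498 ± 131 CPM in the GFP+ sorts (SD, n = 4 mice) and 33.4 ± 1.00 CPM in the CD45+ sorts (n = 2 mice), a change of 3.89 ± 0.36. Trem2 had 83.3 ± 17.4 CPM in the GFP+ and 1877 ± 561 CPM in the CD45+ sorts, a change of -4.47 ± 0.30. Sparc changed by -6.23 ± 0.47 and Cst7 by -4.79 ± 0.41, while Msr1, a scavenger receptor of macrophages, changed by 3.39 ± 0.70. The comparison of the whole sorts gave 1983 of 6155 genes past an adjusted p of 0.05 (edgeR), 945 higher and 1038 lower in GFP+ sorts, and 1091 without mouse 295, which leaves 1 CD45+ library. With myeloid cells only, which leaves out lymphocytes and neutrophils, Ccr2 changed by 4.73 ± 0.31 and Trem2 by -3.82 ± 0.27. Microglia were then 659 of 684 cells of CD45+ mouse 295 and 500 of 528 of CD45+ mouse 301. Macrophages were 47 of 49 cells of GFP+ mouse 230, 82 of 83 of GFP+ mouse 301 and all cells of the other GFP+ mice. This alternative thus sets macrophages against microglia and does not remove the make-up of the sorts. With 2 CD45+ mice, of which mouse 301 gave both sorts and 295 received the control antibody, the sort could not be separated from single mice.

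The largest rises in the GFP+ sorts were those of Nr4a1 (6.88), a factor of patrolling monocytes, Krt80 (5.66), Cd300e (5.25), Gpr141 (5.18), Pla2g7 (5.15), Ace (4.96), Treml4 (4.93), Gda (4.82), Trem3 (4.81) and Sirpb1c (4.77). The largest falls were those of Lrrc3 (-6.91), Tspan7 (-6.89), Syngr1 (-6.88), Pmp22 (-6.54), Cd34 (-6.31), Sparc, Serpine2 (-6.05), Fcrls (-5.80), Gpr84 (-5.72) and Fscn1 (-5.70). On the lower side Nr4a1, Lrrc3 and Tspan7 rested on 1 UMI and Krt80, Gpr141 and Gpr84 on 3, so their fitted values are no bounds. Gpr141 (7.81) and Treml4 (8.46) were larger without mouse 295, and Cd300e (8.48) without the CD45+ sort of mouse 301. All 24 monocyte-derived macrophage genes rose, including Fn1 (4.13) and Ifitm6 (3.99), with the same count adjusted over the list alone (adjusted p = 0.046 with an estimated correlation). Of 23 homeostatic microglia genes 22 fell (adjusted p = 0.093 with an estimated correlation), and of 24 tested late DAM genes 2 rose and 20 fell (adjusted p = 0.046 with an estimated correlation). Of 9 MHC class II genes 7 rose, including H2-Eb1 (2.73), with an adjusted p = 0.18 with an estimated correlation. Of 25 tested lysosome genes 23 fell (adjusted p = 0.077 with an estimated correlation). Apoe fell by 1.11 and Clec7a fell by 1.13. Neither passed when the CD45+ plate of the WT chimera was added, with adjusted p-values of 0.12 for Apoe and 0.38 for Clec7a. Apoe was not past with myeloid cells only (-0.46 ± 0.23, 0.12) or without the CD45+ sort of mouse 301 (0.055), nor was Clec7a without that sort (0.053), mouse 295 (0.064) or mouse 265 (0.098). Without the CD45+ sort of mouse 301 or without mouse 295 a single CD45+ library is left, and the spread then comes from the GFP+ sorts. Cd274 changed by -0.23 ± 0.45 (adjusted p = 0.75).

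Few microglia were found among GFP+ cells, with 2 of 199 cells in IgG mouse 230 (1.01%, exact 95% interval 0.122 to 3.58%) and 1 of 195 in anti-PD-L1 mouse 301 (0.513%, 0.0130 to 2.82%). In anti-PD-L1 mouse 224, 0 of 294 cells were microglia, and in mouse 265 0 of 285. An upper limit of 3 counts over all cells allows shares of up to 1.02% and 1.05%. The exact 95% intervals, as given for the other mice, reach 1.25% and 1.29%. Macrophages made up 23.6% of GFP+ cells in mouse 230 (exact 95% interval 17.9 to 30.1%), 44.9% in mouse 224 (39.1 to 50.8%), 45.3% in mouse 265 (39.4 to 51.2%) and 42.1% in mouse 301 (35.04 to 49.3%). Lymphocytes were 54.3%, 48.0%, 41.4% and 49.2% of the GFP+ cells of these mice in the same order, and neutrophils 21.1%, 7.14%, 13.3% and 8.21%. Among the CD45+ sorts, microglia were 90.4% of cells in IgG mouse 295 (exact 95% interval 88.0 to 92.4%), 92.6% in the untreated WT mouse 267 (89.4 to 95.1%) and 68.5% in anti-PD-L1 mouse 301 (65.0 to 71.9%), where lymphocytes made up 26.6% (23.4 to 29.9%). The border macrophage cluster held 3 cells of the GFP+ sorts, against 6 of the 25 macrophages of CD45+ mouse 295, 4 of 28 of mouse 301 and 3 of 14 of mouse 267. A single mouse represented each CD45+ group and the GFP+ IgG group, so antibody effects in chimeras were not tested; the intervals cover counting error only.

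**Figure D3:**
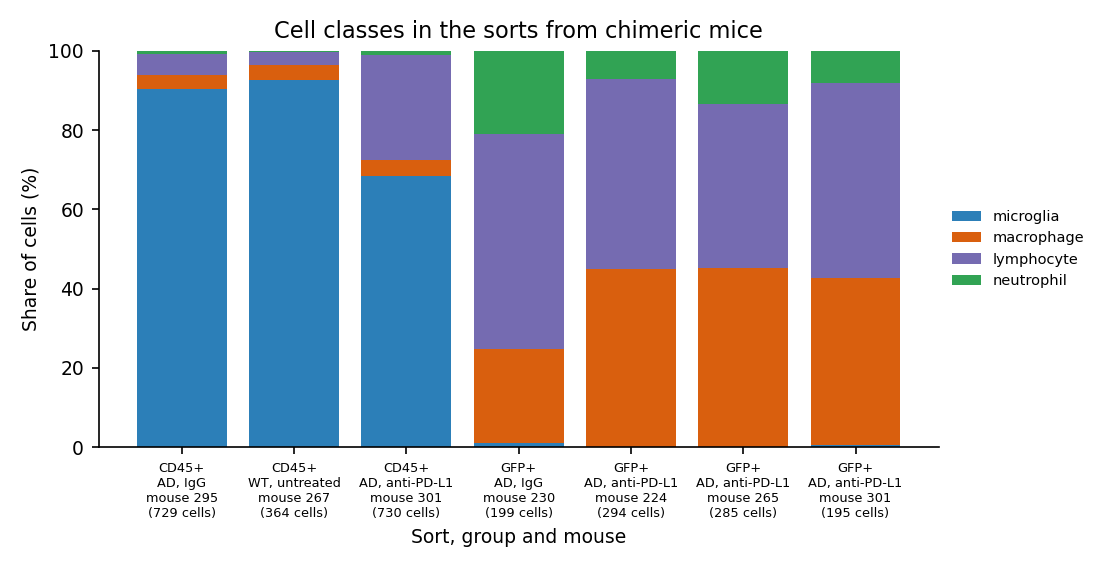
Share of cells in percent (vertical axis) of the 4 classes, microglia, macrophage, lymphocyte and neutrophil, in each sort of each chimeric mouse (horizontal axis); bars are single mice. Microglia make up 68.5 to 92.6% of the CD45+ sorts and 0 to 1.01% of the GFP+ sorts.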

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

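The tests of explanations for the macrophage and lymphocyte shares, the test of the difference between classes, the lymphocyte comparisons by genotype and the counts over other splits of the mice were chosen only after the results were seen; the tests of depth, cell number and an equal response were fixed before the results they measure.

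The TREM2 genotype changed 785 genes in the microglia class and 1 gene in the macrophage class, and 46 genes had a genotype effect that differed between the classes, led by Cd74, H2-Aa and Axl. The tables argue against lower depth of the macrophage libraries as the whole cause, since microglia libraries thinned to the UMI totals of the macrophage libraries still gave a median of 121 genes (102 to 129 over 20 draws), and microglia libraries of as many cells gave a median of 125.5 (61 to 170). They also argue against an equal response hidden by noise, for genes tested in both classes. Over 218 such genes called in microglia, the median change in macrophages was 0.0363 of that in microglia. This ratio carries no error, and its genes were chosen by their calls in microglia. Genes not tested in macrophages, such as Cst7, are not covered. The change in microglia also includes any shift between the clusters of the class. The splits argue against chance for the 785 genes. Of 100 splits of the mice drawn from 200 possible, 1 gave as many, the real one, and the highest other gave 165. The splits do not separate genotype from sex, since the TREM2-/- mice were all female. For the 1 macrophage gene, 7 of 100 splits gave as many, the highest other 3, so the count alone does not exclude chance. A smaller response of macrophages than of microglia to the loss of TREM2 may be the biological explanation, as a hypothesis, for genes abundant enough to be tested in both.

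The macrophage class took a larger share of the sorted cells in TREM2-/- mice. The tables argue against sex as the cause, since the difference among female mice was 13.3 percentage points and each TREM2-/- mouse lay above each TREM2+/+ mouse there. A loss of microglia from the Tmem119neg-mid gate stays open: Tmem119 RNA was higher in TREM2-/- microglia, so more of them may have fallen outside the gate, which would raise every other class alike. Lymphocytes went along with this under IgG2b (1.78 ± 0.894% in TREM2-/- against 0.330 ± 0.336% in TREM2+/+ mice) and against it under anti-PD-L1 (2.52 ± 0.257% against 3.78 ± 0.833%, SD, n = 3 each), and over both antibodies they differed by 0.0943 percentage points (exact p = 0.87). Among cells that were not microglia, the macrophage share was 80.3 ± 7.49% against 66.5 ± 13.8% (SD, n = 6 each), a difference of 13.8 percentage points with an exact p of 0.05, which was not under the threshold. An accumulation of macrophages without TREM2 and the gate cannot be told apart, because the same gate was used for all 12 mice. The mitochondrial limit stays open too, since it removed 0 to 24 wells per plate of TREM2-/- mice against 23 to 73 of TREM2+/+ mice and was not varied.

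The lymphocyte share under anti-PD-L1 was further above that under IgG2b in TREM2+/+ than in TREM2-/- mice, by a difference of -2.70 percentage points between the antibody effects (exact permutation p = 0.005, 0.02 adjusted over 4 classes, the smallest p possible; genotype labels were permuted, so that a genotype effect is assumed absent). The plate series stays open, since on the AB9 plates alone the difference in TREM2+/+ mice was 0.931 percentage points (exact p = 0.3), against 4.75 on the AB10 plates (exact p = 0.1, the smallest possible), and control mouse 492 lay above anti-PD-L1 mice 496 and 498 on AB9. The AB10 value also includes the further AB10 plate of each anti-PD-L1 mouse, which no IgG2b mouse had. A general loss of sort purity stays open too: the T cell cluster was higher by 3.38 percentage points and the B cell cluster by 0.0730, but no B cell was seen under IgG2b, so a ratio for B cells could not be formed. An entry of T cells under PD-L1 blockade may explain the difference and was not tested apart from these, and the CD11b+ gate should remove most lymphocytes.

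Antibody effects in 3 against 3 mice have 10 splits, too few for a share under 0.05. The real and highest other counts were 2 and 16 for TREM2+/+ microglia, 1 and 2 for TREM2-/- microglia, 6 and 1 for TREM2+/+ macrophages, and 0 and 1 for TREM2-/- macrophages. The 16 genes point to a structure of the samples: among TREM2+/+ microglia the 4 splits with both female mice, 492 and 493, on the same side gave 1, 2, 7 and 16 genes, and the 5 remaining splits apart from the real one gave 0, so that the structure went along with sex. The antibody fits had no term for sex, and none was tried. The tests of the difference between genotypes gave 0 genes in microglia with up to 13 in other splits, and 0 in macrophages with up to 26. Every split gives at least 0 genes, so the splits say nothing about those counts. The split with 13 parted the TREM2+/+ mice as the split with 16 did, and the split with 26 exchanged the antibody labels of all TREM2+/+ mice, which turns the difference between the antibody effects into their sum. The CD45+ experiment gave 0 genes as well, with up to 2 in the other splits.

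A sample far from the others of its group was found in 4 of 41 tests, each of 1 measure in 1 group. Chance gives about 1 in 20 of independent tests. These tests share mice and are not independent, and the 4 include both the microglia and the macrophage share of mouse 498. An excess over chance is therefore not shown. CD45+ IgG mouse 997 had 11.6% lymphocytes, and the next mouse 3.82%. With finer clusters no IgG mouse was above 3.82%, since the finer lymphocyte clusters left out most IgG cells of the B cell cluster. TREM2+/+ mouse 498 had 82.0% microglia, with the next at 90.1%, and 11.8% macrophages, with the next at 5.86%. CD45+ anti-PD-L1 mouse 996 had 449.7 CPM of Clec7a in microglia, with the next at 261.

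A signal was also found on the 2 chimera plates whose sort labels disagree, which no comparison used. Plate 1 of mouse 267 held 48.4% macrophages and 50% lymphocytes, and plate 1 of mouse 295 held 59.9% macrophages and 11.9% neutrophils, against at most 3.85%, 26.6% and 1.10% in the CD45+ sorts of chimeras. The GFP+ sorts, the other sort that the labels name, held 23.6 to 45.3% macrophages, 41.4 to 54.3% lymphocytes, 7.14 to 21.1% neutrophils and at most 1.01% microglia, nearer to the 0.532% and 0% microglia of these plates than the 68.5% or more of the CD45+ sorts.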

How the results depend on the processing

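The alternatives AB9 plates only, AB10 plates only for shares, without the mice of 1 plate, without the mice aged 7 months, without the border-like cluster, without 1 plate of mouse 997, and without the most abundant genes were chosen after seeing the data.

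The 785 genes of the genotype effect in microglia ranged from 554 to 819 under the other alternatives and from 582 to 942 with a mouse left out, and were 159 on the AB9 plates alone. These have fewer mice, fewer cells and fewer genes tested. With library size alone 772 genes passed, 50.4% of them higher in TREM2-/- mice against 39.0% with TMM. Summing all cells of the sort, which adds macrophages, reversed Cd74 (0.72), H2-Aa (0.98), Lyz2 (0.0588), H2-Ab1 (1.03), H2-Eb1 (1.32) and Il1b (0.0781) in that comparison. Set in place of the macrophage class, the same sum consists mostly of microglia. It reversed Apoe (-0.53) for genotype and Aif1 (0.0336) for the antibody in TREM2+/+ mice, which are thus not macrophage values.

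Counts that started from 6 genes or fewer moved often, and for those the cause was not tested. For macrophages, summing all cells replaces the class by the whole sort. Microglia made up 68.3% (mouse 507) to 93.4% (mouse 492) of the cells of a mouse there. Macrophage counts with all cells summed are therefore not results of macrophages alone. The genotype effect in macrophages (1) was 2 under DESeq2, 17 without a filter, 720 with all cells summed, 3 with sex as a covariate, 5 in female mice, 3 without the mice of 1 plate, 2 without the border-like cluster and 1 to 3 with a mouse left out. The antibody effect in TREM2+/+ microglia (2) was 7 under library size alone, 0 under DESeq2, 26 without a filter, 1 with at least 500 UMIs, 7 with all cells summed, 32 on AB10 plates, 15 on AB9 plates, 6 without the mice of 1 plate, 9 without those of 7 months and 0 to 11 with a mouse left out. In TREM2-/- microglia (1) it was 2 under library size alone, 20 without a filter, 0 without the mice of 1 plate, 3 without those of 7 months and 1 to 4 with a mouse left out. In TREM2+/+ macrophages (6) it was 22 under library size alone (20 higher and 2 lower, against 2 higher and 4 lower), 22 under DESeq2, 24 without a filter, 33 on AB10 plates, where the IgG2b group was mouse 495 alone, 16 without the mice of 1 plate, 0 without the border-like cluster, which also dropped mouse 495 for its 18 cells (0 without that mouse alone), and 0 to 45 with a mouse left out. In TREM2-/- macrophages (0) it was 1 under DESeq2, 1 with all cells summed, 2 without the mice of 1 plate and 0 to 5 with a mouse left out. The test of the difference between genotypes (0) was 3 in microglia without a filter and 3 with all cells summed, and 3 in macrophages with all cells summed and 0 to 1 with a mouse left out. The antibody effect in the CD45+ experiment (0) was 14 without a filter and 0 to 1 with a mouse left out. The GFP+ comparison ranged from 1091 to 2156 genes with a mouse left out, with a single CD45+ library in the fits without mouse 295 (1091) or the CD45+ sort of mouse 301 (1717).

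Among shares, the genotype differences of microglia and macrophages kept their direction under each alternative run, and in female mice alone the microglia (-14.6) and macrophage (13.3) differences had too few mice for an exact p under 0.05. The antibody effect on lymphocytes had an exact p of 0.015 (0.06 adjusted over 4 classes), which was 0.875 on AB9 plates (0.138), and female mice (2.38) were too few for an exact p under 0.05. On the AB9 plates and without the mice of 1 plate the TREM2-/- IgG2b group was mouse 488 alone. The antibody difference of lymphocytes in the CD45+ experiment, -1.72, was -0.0218 with finer clusters, where the mean under IgG was 2.149% against 3.85%. Reversed values belonged to differences not past the threshold, and the cause was not tested. For the antibody these were microglia on AB9 plates (3.12), in TREM2+/+ mice on AB9 plates (0.0802) and in TREM2-/- mice on AB10 plates (-0.0544), macrophages with at least 500 UMIs (0.260) and on AB10 plates (0.563), in TREM2+/+ mice on AB9 plates (-0.222), lymphocytes in TREM2-/- mice on AB9 plates (-0.656), and neutrophils on AB10 plates (0.0316), in TREM2+/+ mice with at least 500 UMIs (-0.0398) and on AB9 plates (-0.790). The genotype difference of lymphocytes was -0.527 in female mice and -0.278 on AB10 plates. In the CD45+ experiment neutrophils were -0.0233 with at least 500 UMIs and -0.258 in the AB6 series, and the difference between genotypes in neutrophils was 0.285 on AB9 plates.

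With a mouse left out, shares that reversed or passed ranged as follows, in percentage points, and the cause was not tested. The antibody difference ranged from -3.48 to 0.329 for microglia and from -2.26 to 1.69 for macrophages, from -0.738 to 0.0242 for neutrophils, and in the CD45+ experiment from -0.987 to -0.453 for macrophages and from -2.63 to 0.0313 for lymphocytes. In TREM2-/- mice it ranged from -1.83 to 5.78 for microglia and from -6.10 to 1.80 for macrophages, and in TREM2+/+ mice from -0.835 to 2.99 for macrophages and from -0.506 to 0.658 for neutrophils. The difference between genotypes in the antibody effect ranged from -7.67 to 0.223 for macrophages, and the genotype difference of lymphocytes from -0.152 to 0.320.

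Of 224 counts of genes under alternatives 148 stayed within 1.5 times the main count and 76 did not. Of 5032 values of named genes 4524 were marked as the same, 225 no longer passed, 83 newly passed, 192 were marked as moved and 8 as reversed. Of 404 share values 366 kept direction and side of the threshold, 6 no longer passed, 1 newly passed and 31 reversed. No paired analysis was possible because the groups share no replicate numbers apart from chimera mouse 301, and fewer than 2 pairs can be formed. Fits of the macrophage class on AB9 plates alone could not be estimated, since 4 libraries had at least 20 cells, and the macrophage class of the CD45+ experiment was not run because its mice had 2 to 19 such cells. Depth limited the macrophage class to 570 tested genes, against 7520 in microglia.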

Other observations

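The comparison of lymphocyte shares by plate series was chosen after the result was seen.

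Plate 1 of chimera mouse 267 held 188 cells, of which 1 was microglia (0.532%, exact 95% interval 0.0135 to 2.93%) and 2 were neutrophils (1.06%). Plate 1 of mouse 295 held 227 cells, of which 0 were microglia, 136 were macrophages and 64 were lymphocytes (28.2%, 22.4 to 34.5%). The labels of both plates name CD45+GFP+ in one place and CD45+ in another, and these plates entered no group.

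By plate series, the lymphocyte share of TREM2+/+ mice under anti-PD-L1 was 5.96%, 3.99% and 4.62% on AB10 plates for mice 493, 496 and 498, and 2.08%, 1.05% and 1.38% on AB9 plates. Under IgG2b, mouse 492 had 0 of 310 cells on AB10 and 4 of 285 on AB9, mouse 494 had 0 of 291 and 0 of 324, and mouse 495 had 1 of 308 and 1 of 323.

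The genes Ddx3y and Eif2s3y of the Y chromosome had 0 UMIs in the microglia of all 6 TREM2-/- mice, which the labels give as female, and Xist was higher in TREM2-/- mice with a change of 1.74 ± 0.50 (adjusted p = 0.018). Among female mice only its change was 0.23 ± 0.28 (0.74) and with sex as a covariate 0.22 ± 0.29 (0.76). The call was also lost under DESeq2 (0.64), without the mice of 1 plate (0.055) and without mouse 487 (0.068), 489 (0.051) or 498 (0.052).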
